A study of Mus musculus with 9 samples.

How the data were processed

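Liver RNA of 9 adult male C57Bl6 mice was measured by RNA sequencing of poly(A)-selected libraries on an Illumina HiSeq2500. Per the labels, the mice were 16 to 20 weeks old, had fasted for 6 h, and gave a liver punch of about 100 mg each. The labels give 50 M paired-end reads of 50 bp per library (M, mega). There were 3 groups of 3 mice. Mice labelled Gcgr+/+ were given PBS, mice labelled Gcgr-/- were given PBS, and mice labelled Gcgr+/+ were given 10 mg/kg of a humanized monoclonal antibody to the glucagon receptor, injected into the peritoneum weekly over 10 days. No batch is labelled.

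The submitters' processing notes name FastQC, TopHat2 2.0, SAMtools and the mouse genome build mm9. The tools that counted reads and scaled the counts are not given in the sources used here. The deposited table holds a signal per Ensembl gene and library, for 37583 genes, called normalized counts here. Some of the low values lie on steps like those of read counts divided by a factor per library, and most do not. No value lay under 1, and 15160 genes sat at that floor in all 9 libraries. The normalized values of a library summed to between 42.4 and 52.1 M. Divided by the worth of 1 read, only 40.8% to 45.8% of a library's values under 10 reads were whole within 0.01 read. Whole reads could therefore not be recovered, and tests that model read counts were not run.

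The commonest value above the floor was taken as the worth of 1 read in a library, and it lay between 1.50 and 4.74 normalized counts. On this estimate the libraries held from 10.99 to 30.1 M reads assigned to genes. The voom precision weights named below were computed from these estimated reads, which are not all whole, with values at the floor taken as no reads. The median tested gene had a mean value of 293 normalized counts.

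Values were taken as log2(value + 1). A gene was tested when its value was above 1 in at least 3 of the 9 libraries, which left 20029 genes and excluded 17554. The filter had been written as at least 1, and was read as above 1 once the floor of 1 was seen in the table. Group means were fitted over all 9 libraries with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend and robust estimation), with group as the single factor. The contrasts were knockout-labelled against wild type, antibody-labelled against wild type, and antibody-labelled against knockout-labelled. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a contrast and a threshold of 0.05. Fold changes are given on the log2 scale with the standard error (SE) of the fit, and group levels as the mean of normalized counts ± SD. The smallest p that a permutation of 3 libraries against 3 allows is 0.1, so no permutation test was run for single genes.

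Lists of genes were tested with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 33 lists of a contrast. Camera with an estimated correlation and limma's fry were run beside it. There were 22 functional lists: amino acid catabolism, urea cycle, amino acid transporters, gluconeogenesis, cAMP and CREB responsive genes, glycolysis and glycogen, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation and ketogenesis, bile acid synthesis and transport, xenobiotic metabolism, integrated stress response, growth hormone signalling, male-biased and female-biased liver genes, circadian clock, acute phase, interferon response, cell cycle, iron and haem, and pericentral and periportal hepatocyte genes. There were 11 lists of cell type markers: Kupffer cells and macrophages, lymphocytes, neutrophils, sinusoidal endothelial cells, stellate cells and fibroblasts, cholangiocytes, erythroid cells, pancreatic acinar cells, adipocytes, skeletal muscle and hepatocytes. Of 552 listed genes, 549 were matched to the table and 524 were tested. Symbols were matched with the table's own symbols, with older symbols, and with GENCODE M21 names for the 32860 Ensembl IDs it shares with the table. Coordinates are those of the table, in mm9.

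Genes were named by a fixed rule. Gcgr was always given. For each contrast the rule took the 5 highest and 5 lowest fold changes among genes past the threshold whose groups did not overlap and whose higher group lay at or above the median level. It also took the list members with the smallest adjusted p, up to 3 for the amino acid and urea cycle lists and up to 2 for the others, and every list member past the threshold in the direct contrast. Gls2, Cps1, Slc7a2, Slc38a5, Pck1, G6pc, Fgf21 and Glul were given whatever their p. Other list members that are named were chosen after their values were seen. The agreement of the effects against wild type was measured as the covariance of the fold changes across genes, beside 100 simulations of unchanged groups that share the same controls.

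The groups, tests, thresholds, lists and naming rule were chosen before the data were examined, and so were the alternatives, apart from weights per library and voom precision weights. The alternatives were a pseudocount of 0.1, no filter, a floor of 10, median centring, quantile normalization, no trend and no robust estimation, the replicate number as a block, fits of only the 6 libraries compared, sums over genes with the same symbol, an added minimum log2 fold change of 1, lists without shared genes, and leaving out each library in turn. The fit was also tested on simulated data built from the table. Among genes above the median level that were changed 2-fold in the simulation, it called 31 of 35 in knockout-labelled against wild type, 26 of 29 in antibody-labelled against wild type, and 34 of 36 in the direct contrast. Among those changed 1.5-fold it called 9 of 32, 9 of 30 and 13 of 31. False calls were 7 of 98, 4 of 92 and 5 of 103. Genes were drawn independently, and all libraries had one spread per gene. No simulated library was therefore set apart from its group, as knockout-labelled library 1 was in the real data. The adjusted threshold also loosens with the number of calls, and the real contrasts had 31, 268 and 56. The shares called in the simulation need not hold for the real contrasts. In simulated lists of 25 genes, run for antibody-labelled against wild type alone, camera called 20 of 20 lists shifted by 0.4 on the log2 scale and 1 of 80 unshifted lists. The genes of these lists were drawn independently. In the real lists the estimated correlation between genes ranged from -0.018 for cell cycle to 0.825 for Kupffer cells and macrophages. The simulation therefore does not show how often camera calls unshifted lists of correlated genes.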

Results

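Liver RNA was sequenced from 9 mice in 3 groups of 3: Gcgr+/+ mice given PBS (wild type), mice labelled Gcgr-/- given PBS (knockout-labelled) and mice labelled Gcgr+/+ given an antibody to the glucagon receptor (antibody-labelled). The series used both ways of interrupting glucagon signalling to look for liver genes that could link the loss of the signal to the growth of pancreatic alpha cells, with amino acid handling in view. Estimated reads assigned to genes were 21.7, 30.1 and 21.9 M in the wild-type libraries 1 to 3. They were 10.99, 25.7 and 21.6 M in the knockout-labelled libraries and 22.8, 24.5 and 25.2 M in the antibody-labelled libraries. The 10 genes with the highest values held between 6.26% and 8.55% of a library's normalized counts. The first principal component held 23.1% of the variance and set knockout-labelled library 1, the one with the fewest reads, at 43.3, with the other 8 libraries between -19.0 and 9.87. The second held 22.1% and placed the wild-type libraries between 13.5 and 21.4, the knockout-labelled between 1.86 and 10.9, and the antibody-labelled between -26.9 and -19.1.

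Gcgr, which encodes the glucagon receptor, was low in the libraries labelled as antibody-treated and not in those labelled as knockout. Gcgr (ENSMUSG00000025127, mm9 chromosome 11, 120392013 to 120400402, plus strand) had 18521 ± 993 normalized counts in wild type (SD, n = 3) and 22717 ± 4093 in knockout-labelled libraries (SD, n = 3), or 123% of wild type. The antibody-labelled libraries held 2192 ± 351 normalized counts (SD, n = 3), or 11.8% of wild type. Gcgr did not pass the test in knockout-labelled against wild type (log2 fold change 0.28, SE 0.15, adjusted p = 0.434). It fell by 3.09 on the log2 scale in antibody-labelled against wild type (SE 0.15, adjusted p = 2.29e-06) and stood at -3.37 in antibody-labelled against knockout-labelled (SE 0.15, adjusted p = 8.37e-07). All 9 libraries followed this pattern: the antibody-labelled libraries held 1808 to 2496 normalized counts, the knockout-labelled 19656 to 27365, and the wild type 17565 to 19547. The estimated reads behind these values were 1032 to 11676 per library. The labels do not say which part of the gene is disrupted in the knockout, and a value per gene does not show single exons. All groups are named by their labels below, with none exchanged.

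**Figure D1:**
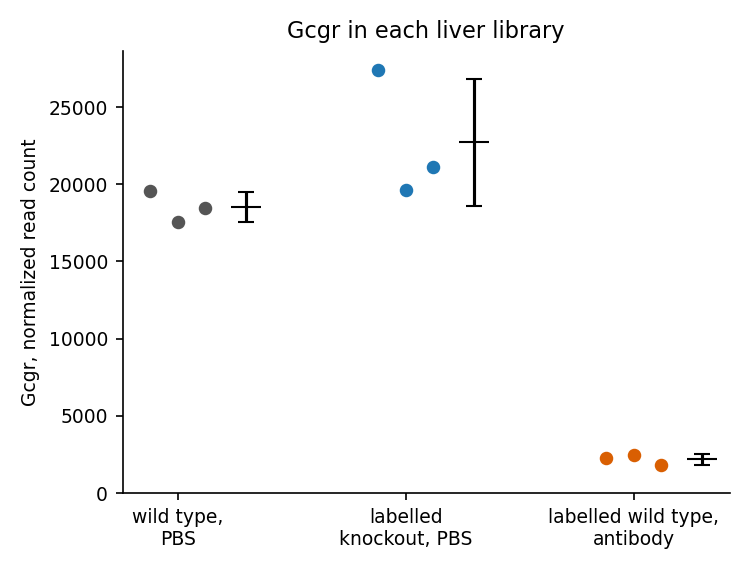
Gcgr in normalized read counts for each of the 9 liver libraries, by labelled group, with the mean and SD of 3 libraries in black. The antibody-labelled libraries lie between 1808 and 2496, below the 17565 to 27365 of all other libraries.

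Knockout-labelled against wild type asks which liver genes differ when the receptor gene is labelled as disrupted. Aqp8, a water channel (ENSMUSG00000030762, chromosome 7, 130605808 to 130611517), rose 3.26-fold, from 870 ± 199 to 2825 ± 561 normalized counts (SD, n = 3 each, log2 fold change 1.70, SE 0.18, adjusted p = 0.00664). Got1, the cytosolic aspartate aminotransferase (ENSMUSG00000025190, chromosome 19, 43574242 to 43599095), went from 27445 ± 4328 to 7539 ± 2950 (SD, n = 3 each, log2 fold change -1.93, SE 0.26, adjusted p = 0.0284). Slc7a2, a transporter of cationic amino acids (ENSMUSG00000031596, chromosome 8, 41947750 to 42007662), went from 72236 ± 17430 to 32652 ± 1256 (SD, n = 3 each, log2 fold change -1.12, SE 0.17, adjusted p = 0.0284). Of 20029 genes tested, 31 passed, 12 higher and 19 lower. At an unadjusted p under 0.05 there were 2758.

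Ly6d, a surface protein, rose by 2.14 on the log2 scale (adjusted p = 0.0284), with 101 ± 35.5 normalized counts in wild type and 433 ± 55.2 in knockout-labelled libraries (SD, n = 3 each). Eif4e3.1 (log2 fold change 1.34, adjusted p = 0.0489), Rogdi (1.32, adjusted p = 0.0181) and Slc17a4, of a phosphate transporter family (1.19, adjusted p = 0.0284), were the other highest under the naming rule. The other lowest under it were F830016B08Rik (-1.34, adjusted p = 0.00664), Pogk (-1.17, adjusted p = 0.0284) and Gm4963 (-1.09, adjusted p = 0.0284). The groups did not overlap in all 31 genes, as in 16.4% of tested genes, where chance gives 10%. Of the genes given whatever their p, all but Slc7a2 did not pass. Gls2, the liver glutaminase, was at -1.18 (adjusted p = 0.139) and Cps1, the first enzyme of the urea cycle, at 0.09 (adjusted p = 0.876). Slc38a5, a glutamine transporter near the floor, was at 0.88 (adjusted p = 0.490). Pck1 and G6pc, enzymes of glucose production, were at -0.11 (adjusted p = 0.904) and -0.39 (adjusted p = 0.639). Fgf21, a liver hormone, was at 0.46 (adjusted p = 0.806) and Glul, glutamine synthetase, at 0.11 (adjusted p = 0.712).

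Of 33 lists, 6 passed camera at the preset correlation in knockout-labelled against wild type, and 0 passed with an estimated correlation, where 1 had an unadjusted p under 0.05. Limma's fry, which asks whether a list's genes move one way, also called 0, with 3 at an unadjusted p under 0.05. Amino acid catabolism was lower (adjusted p = 0.0301, and adjusted p = 0.772 with an estimated correlation), with 1 lower gene of 50 over all genes, Got1, and with 2 higher and 8 lower adjusted over the list alone. Its median was -0.10, and 0.02 without knockout-labelled library 2 (adjusted p = 0.912), and it did not pass without wild-type library 1 (adjusted p = 0.0532) or without genes shared with other lists (adjusted p = 0.0702). The higher pair, chosen after their values were seen, were Amt of glycine cleavage at 0.40 and Bhmt, which remethylates homocysteine, at 0.65. Amino acid transporters were lower (adjusted p = 0.0301, and adjusted p = 0.772 with an estimated correlation), with 1 lower of 29, Slc7a2. This list did not pass without wild-type libraries 1 or 3 (adjusted p = 0.0647 and 0.0840) or knockout-labelled libraries 2 or 3 (adjusted p = 0.141 and 0.0750), nor without shared genes (adjusted p = 0.0702). With p adjusted over the list alone, 4 transporters were lower, the others being Slc3a1 at -0.92, Slc1a2 at -0.71 and Slc25a22 at -0.50, chosen after their values were seen. The integrated stress response list was higher (adjusted p = 0.00152, and adjusted p = 0.155 with an estimated correlation), with 0 of 22 past limma's test over all genes. Adjusted over the list alone, 4 were higher: Atf3 at 1.85, Gdf15 at 1.44, Trib3 at 0.79 and Eif4ebp1 at 0.45, chosen after their values were seen. Atf3 and Trib3 are stress-induced regulators, and Gdf15 is a secreted stress protein.

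Cholesterol synthesis was higher (adjusted p = 0.0301, and adjusted p = 0.772 with an estimated correlation), with 0 of 24 genes past the threshold both over all genes and adjusted over the list alone, a median log2 fold change of 0.17 and 16 positive values. It did not pass without wild-type library 3 (adjusted p = 0.365) or knockout-labelled library 2 (adjusted p = 0.263), nor with library weights (adjusted p = 0.0783). Pericentral hepatocyte genes were lower (adjusted p = 0.0245, and adjusted p = 0.772 with an estimated correlation), with 0 of 20 past, and did not pass without knockout-labelled library 2 (adjusted p = 0.141). With p adjusted over the list alone, 2 were lower: Oat, which breaks down ornithine, at -1.25 and Slc1a2, a glutamate transporter, at -0.71, chosen after their values were seen. Markers of Kupffer cells and macrophages were higher (median 0.21 over 12 genes, adjusted p = 0.0301, and adjusted p = 0.772 with an estimated correlation), with 0 of 12 past, beside the lower amino acid lists in the same libraries. This call ended without wild-type library 2 (adjusted p = 0.268) or knockout-labelled libraries 1 or 3 (adjusted p = 0.557 and 0.0540), and with voom precision weights (adjusted p = 0.0516). The urea cycle list did not pass (adjusted p = 0.181), with 0 of 8 past and 2 lower adjusted over the list alone, Slc25a15 at -0.79 and Ass1 at -0.53, chosen after their values were seen. The other lists had adjusted p from 0.0573 to 0.727. No list's median, mean and test differed in sign in this contrast.

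The 31 genes became 154 without knockout-labelled library 2, 86 without wild-type library 3, 15 without knockout-labelled library 3, 8 without knockout-labelled library 1, 4 and 16 without wild-type libraries 1 and 2, 7 and 16 without antibody-labelled libraries 2 and 3, and 0 without the trend and robust estimation of limma (2402 at an unadjusted p under 0.05). They became 54 with voom precision weights, 15 in a fit of only the 6 libraries compared, and 3 with no filter. Without the trend and robust estimation, 1 of the 6 lists passed, the integrated stress response. Over 19 alternatives the calls of Aqp8 and F830016B08Rik held in 18, Rogdi in 16, Got1, Ly6d, Slc17a4 and Gm4963 in 12, Pogk in 11, Slc7a2 in 10 and Eif4e3.1 in 7.

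Antibody-labelled against wild type asks which liver genes differ when the receptor is labelled as blocked by antibody. By camera at the preset correlation, the lists of amino acid catabolism, the urea cycle and amino acid transporters fell, and those of cholesterol synthesis and of glycolysis and glycogen rose. None of these calls held with an estimated correlation (adjusted p = 0.197, 0.265, 0.361, 0.361 and 0.361). Members that did not pass were 39 of 50, 6 of 8, 26 of 29, 22 of 24 and 18 of 21. Got1 went from 27445 ± 4328 to 3062 ± 436 normalized counts (SD, n = 3 each, log2 fold change -3.16, SE 0.26, adjusted p = 8.92e-04). Cav1, the coat protein of caveolae (ENSMUSG00000007655, chromosome 6, 17256335 to 17291452), rose 11.97-fold, from 268 ± 107 to 3094 ± 698 (SD, n = 3 each, log2 fold change 3.58, SE 0.31, adjusted p = 0.00144). Nnmt, which methylates nicotinamide (ENSMUSG00000032271, chromosome 9, 48399982 to 48413258), had the lowest fold change under the naming rule, from 4135 ± 2604 to 50.5 ± 17.7 (SD, n = 3 each, log2 fold change -6.07, SE 0.72, adjusted p = 0.0119). The wild-type libraries held 5869, 5396 and 1141 normalized counts of Nnmt, and its log2 fold change was -6.84 without the third. Its call was lost without antibody-labelled libraries 2 or 3 (adjusted p = 0.0614 and 0.0570) and with voom precision weights (adjusted p = 0.122), against 0.00187 to 0.122 over 19 alternatives. Of 20029 genes, 268 passed, 143 higher and 125 lower. Of these, 159 changed at least 2-fold. At an unadjusted p under 0.05 there were 2057. The groups did not overlap in all 268, as in 19.2% of tested genes, where chance gives 10%.

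The other highest genes under the naming rule were Rgs16, a brake on G protein signalling (log2 fold change 3.13, adjusted p = 0.0129), Pcp4l1 (2.56, adjusted p = 5.33e-04), Aqp8 (2.34, adjusted p = 2.06e-04) and Gpr98, an adhesion receptor (2.17, adjusted p = 0.00889). Beside Nnmt, Got1 and Gcgr, the lowest under the rule were Zap70, a kinase of T cell receptor signalling, at -4.02 (adjusted p = 0.0053) and the antisense transcript 1300015D01Rik at -3.29 (adjusted p = 5.33e-04). Zap70 had 681 ± 269 normalized counts in wild type and 41.7 ± 20.1 in antibody-labelled libraries (SD, n = 3 each), and the 12 tested lymphocyte markers did not pass as a list (adjusted p = 0.949).

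Amino acid catabolism fell, with 11 of 50 genes lower, 0 higher and 39 not past the threshold (camera adjusted p = 2.63e-20, and adjusted p = 0.197 with an estimated correlation). Limma's fry gave it an adjusted p of 0.0325. Oat went from 73516 ± 21982 to 14063 ± 3724 normalized counts (SD, n = 3 each, log2 fold change -2.38, adjusted p = 0.00145). Aass, which starts lysine breakdown, went from 37671 ± 1570 to 16660.0 ± 1630.0 (SD, n = 3 each, log2 fold change -1.18, adjusted p = 0.00165), and Gls2 was at -1.78 (adjusted p = 0.0224), a call that held in 12 of 19 alternatives. Others among the 11, chosen after their values were seen, were Sdsl, Cth, Hgd, Agxt, Mat1a and Cbs, from -1.78 to -0.97. Adjusted over the list alone, 18 genes were lower and 1 was higher, Aspg, an asparaginase, at 0.61, chosen after its value was seen.

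The urea cycle list fell, with 2 of 8 genes lower (adjusted p = 3.42e-07, and adjusted p = 0.265 with an estimated correlation) and 6 lower adjusted over the list alone. The 2 were Ass1, argininosuccinate synthase, at -1.19 (adjusted p = 0.00725) and Slc25a15, the mitochondrial ornithine carrier, at -1.05 (adjusted p = 0.0053), while Cps1 was at -0.43 (adjusted p = 0.476). Amino acid transporters fell, with 3 of 29 lower (adjusted p = 0.00645, and adjusted p = 0.361 with an estimated correlation). They were Slc25a22, a mitochondrial glutamate carrier, at -1.27 (adjusted p = 0.00171), Slc7a2 at -1.27 (adjusted p = 0.00395) and Slc3a1, a subunit of a cystine transporter, at -1.07 (adjusted p = 0.0109). With p adjusted over the list alone, 5 transporters were lower, with Slc43a1 at -1.92 and Slc1a2 at -0.67 as the other members, and 1 was higher, Slc6a9 at 0.59, all 3 chosen after their values were seen. Slc38a5 was at 0.01 (adjusted p = 0.999), with 1.56 ± 0.500 normalized counts against 1.56 ± 0.593 in wild type (SD, n = 3 each), close to the floor of 1. Glul was at 0.19 (adjusted p = 0.700).

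**Figure D2:**
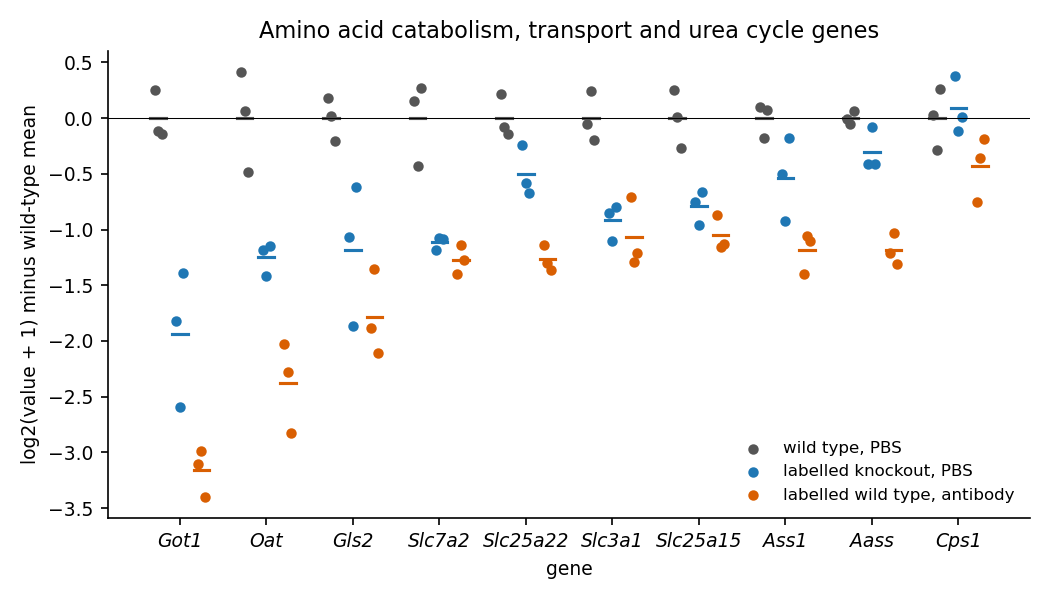
Points are log2(value + 1) of single libraries minus the wild-type mean, for 10 genes of amino acid catabolism, transport and the urea cycle, with a line at the mean of the 3 libraries of a group. Got1 lies lowest, at -1.93 in knockout-labelled and -3.16 in antibody-labelled libraries, and Cps1 at 0.09 and -0.43.

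The cAMP and CREB responsive genes fell, with 1 of 20 lower (adjusted p = 5.40e-05, and adjusted p = 0.0555 with an estimated correlation, fry adjusted p = 0.0325). It was Pde4b, which breaks down cAMP, at -2.13 (adjusted p = 0.0138), and adjusted over the list alone 2 were lower, with Crem, a cAMP-responsive regulator, at -0.69, chosen after its value was seen. Glycolysis and glycogen genes rose, with 3 of 21 higher (adjusted p = 0.00493, and adjusted p = 0.361 with an estimated correlation). There were, adjusted over the list alone, 6 higher and 1 lower, Gys2 of glycogen synthesis at -0.57. The 3 were Pklr, liver pyruvate kinase, at 1.35 (adjusted p = 0.00394), Gbe1, the glycogen branching enzyme, at 1.03 (adjusted p = 0.00343) and Slc2a2, a glucose transporter, at 0.73 (adjusted p = 0.0442). Gys2 and Slc2a2 were chosen after their values were seen. Gluconeogenesis fell as a list with 0 of 15 past limma's test over all genes (adjusted p = 0.0066, and adjusted p = 0.378 with an estimated correlation), and did not pass without wild-type library 1 (adjusted p = 0.0566) or antibody-labelled library 2 (adjusted p = 0.0638). Adjusted over the list alone, 2 were lower, Fbp1 at -0.65 and Ldha at -0.55, chosen after their values were seen. Pck1 was at -0.81 (adjusted p = 0.333), G6pc at -0.58 (adjusted p = 0.649) and Fgf21 at -0.47 (adjusted p = 0.912).

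Cholesterol synthesis rose, with a median log2 fold change of 0.78, 2 of 24 genes higher (adjusted p = 2.02e-12, and adjusted p = 0.361 with an estimated correlation) and, adjusted over the list alone, 15 higher and 1 lower, Ebp at -0.34, chosen after its value was seen. Fdps, a synthase of farnesyl units, was at 1.70 (adjusted p = 0.0243) and Lss, lanosterol synthase, at 0.92 (adjusted p = 0.0162), calls that held in 11 and 13 of 19 alternatives. Fatty acid oxidation and ketogenesis fell, with 1 of 30 lower (adjusted p = 3.42e-07, and adjusted p = 0.378 with an estimated correlation), Cpt1a, which brings fatty acids to mitochondrial oxidation, at -0.63 (adjusted p = 0.0297), a call that held in 11 of 19 alternatives. With p adjusted over the list alone, 4 were lower, with Acot1 at -0.84, Ehhadh at -0.82 and Cpt2 at -0.49 chosen after their values were seen. Fatty acid synthesis did not pass as a list (median 0.18, adjusted p = 0.0921), and 2 of 19 fell: Fads2 at -1.22 (adjusted p = 0.00889) and Elovl5 at -1.05 (adjusted p = 0.0127), which desaturate and elongate polyunsaturated fatty acids. Adjusted over the list alone, 2 were higher, Thrsp at 2.23 and Fasn, fatty acid synthase, at 1.09, and 3 were lower, the last being Fads1 at -0.53. Thrsp, Fasn and Fads1 were chosen after their values were seen. Bile acid synthesis and transport had 0 of 18 past limma's test, over all genes or adjusted over the list alone (adjusted p = 0.529), with a median of -0.07, a mean of 0.03 and a test pointing down.

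The integrated stress response list rose, with 1 of 22 higher (adjusted p = 6.05e-05, and adjusted p = 0.0555 with an estimated correlation, fry adjusted p = 0.0325), Psat1 of serine synthesis at 2.22 (adjusted p = 0.0423), a call that held in 7 of 19 alternatives. With p adjusted over the list alone, 5 were higher, with Nupr1 at 1.06, Trib3 at 0.72, Psph at 0.56 and Eif4ebp1 at 0.35, and 1 lower, Atf5 at -0.61, all 5 chosen after their values were seen. Xenobiotic metabolism rose as a list (adjusted p = 0.00104, and adjusted p = 0.395 with an estimated correlation), with 1 of 26 higher, 2 lower, and 8 higher and 2 lower adjusted over the list alone. Gstm1 was at 0.97 (adjusted p = 0.0232, held in 12 of 19 alternatives) and Gstm2 at -1.03 (adjusted p = 0.00896), glutathione transferases with 20 listed paralogs each, and Por, which passes electrons to cytochromes P450, was at -0.86 (adjusted p = 0.0423, chosen after its value was seen). Acute phase genes fell as a list (adjusted p = 0.00645, and adjusted p = 0.378 with an estimated correlation), with Orm3 higher at 2.14 (adjusted p = 0.0157) and Orm2 lower at -1.36 (adjusted p = 0.0413) of 23, both coding for orosomucoids, calls that held in 14 and 11 of 19 alternatives. Adjusted over the list alone, 2 were higher and 3 lower, with Apcs at 0.54, Mt2 at -2.29 and Mt1 at -1.45 chosen after their values were seen. The interferon response fell as a list with 0 of 21 past limma's test, over all genes or adjusted over the list alone (adjusted p = 0.00153, and adjusted p = 0.438 with an estimated correlation), and a median of -0.33.

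Pericentral hepatocyte genes fell, with 3 of 20 lower (adjusted p = 1.52e-04, and adjusted p = 0.361 with an estimated correlation): Oat, Rhbg, an ammonium transporter, at -1.15 (adjusted p = 0.00463), and Gulo of vitamin C synthesis at -0.66 (adjusted p = 0.0299, chosen after its value was seen). With p adjusted over the list alone, 5 were lower, with Lect2 at -0.84 and Slc1a2 at -0.67, also chosen after their values were seen. Periportal hepatocyte genes fell as a list (adjusted p = 0.0160, and adjusted p = 0.495 with an estimated correlation), with Hsd17b6, a steroid and retinol dehydrogenase, higher at 1.61 (adjusted p = 0.00252), Ass1 and Gls2 lower, and 17 not past. Its median turned from -0.23 to 0.02 without genes shared with other lists (adjusted p = 0.220), and it did not pass without wild-type library 3 (adjusted p = 0.0662) or antibody-labelled library 1 (adjusted p = 0.193). Adjusted over the list alone, 4 were higher and 5 lower. The higher were Hsd17b6, Cdh1 at 0.75, Cyp2f2 at 0.49 and Ctsc at 0.38, and the lower were Sds at -1.91, Gls2, Ass1, Pck1 and Gas2 at -0.70, of which Cdh1, Cyp2f2, Ctsc, Sds and Gas2 were chosen after their values were seen.

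Lists that did not pass included growth hormone signalling with 0 of 12 past limma's test (adjusted p = 0.152) and Igf1, the growth factor, lower at -0.81 adjusted over the list alone, chosen after its value was seen. Male-biased liver genes had 0 of 14 past (adjusted p = 0.916), and Elovl3 was lower at -1.65 adjusted over the list alone, chosen after its value was seen. Female-biased liver genes (adjusted p = 0.529) had a median of 0.25, a mean of -0.23 and a test pointing down, with 1 of 19 lower, Cyp17a1 of steroid synthesis, at -3.02 (adjusted p = 0.0192, held in 11 of 19 alternatives), and also A1bg at -2.35 adjusted over the list alone, chosen after its value was seen. The circadian clock list (adjusted p = 0.416) had 1 of 19 higher, the clock repressor Bhlhe40 at 1.17 (adjusted p = 0.00343), which was also the 1 gene adjusted over the list alone. Iron and haem (adjusted p = 0.530, median 0.15, mean -0.01, test pointing up) had 1 of 13 higher, the iron exporter Slc40a1 at 0.74 (adjusted p = 0.0182), and 1 lower, the transferrin receptor Tfrc at -1.79 (adjusted p = 0.0242), calls that held in 12 and 10 of 19 alternatives. These were also the genes past adjusted over the list alone. Cell cycle had 0 of 21 past limma's test, over all genes or adjusted over the list alone (adjusted p = 0.119).

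Of the cell type markers, 3 lists rose beside these hepatocyte genes, with no member past limma's test over all genes. Stellate cells and fibroblasts had a median of 0.26 over 11 genes (adjusted p = 0.00373, and adjusted p = 0.377 with an estimated correlation), and Col3a1, a fibrillar collagen, was higher at 0.63 adjusted over the list alone, chosen after its value was seen. The stellate list did not pass without wild-type library 3 (adjusted p = 0.0671). Sinusoidal endothelial cells had a median of 0.15 over 10 genes (adjusted p = 0.0195, and adjusted p = 0.438 with an estimated correlation), and did not pass with median centring (adjusted p = 0.0874) or without wild-type library 2 (adjusted p = 0.190) or antibody-labelled library 3 (adjusted p = 0.208). Kupffer cells and macrophages had a median of 0.17 over 12 genes (adjusted p = 0.0249, and adjusted p = 0.605 with an estimated correlation). They did not pass with median centring (adjusted p = 0.0720), without wild-type libraries 1 or 2 (adjusted p = 0.0895 and 0.345), or without antibody-labelled libraries 2 or 3 (adjusted p = 0.0847 and 0.0765). The lists that did not pass were lymphocytes (median 0.03, mean -0.07, test pointing up), neutrophils (adjusted p = 0.119), cholangiocytes (adjusted p = 0.550), erythroid cells (adjusted p = 0.0921), pancreatic acinar cells (adjusted p = 0.530), adipocytes (adjusted p = 0.257), skeletal muscle (adjusted p = 0.949) and hepatocytes (adjusted p = 0.290).

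**Figure D3:**
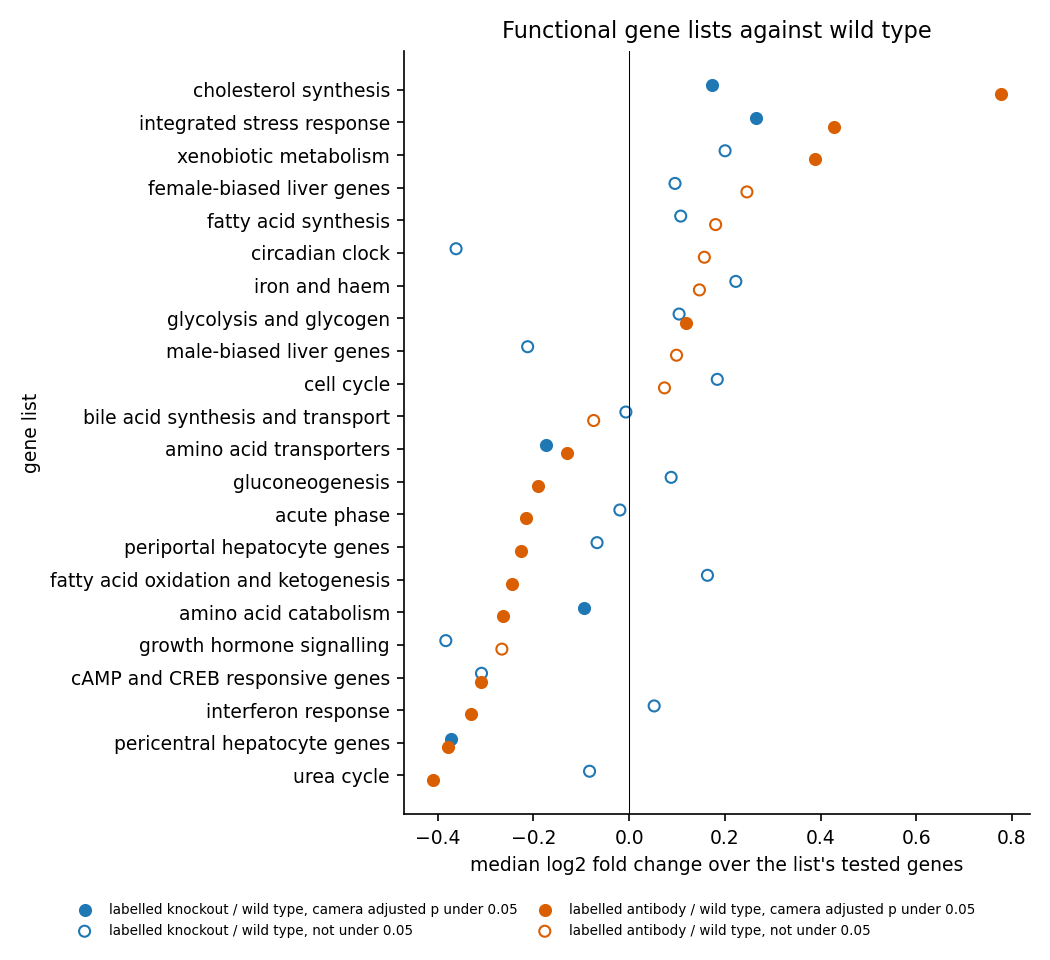
Median log2 fold change of each functional list's tested genes against wild type, for knockout-labelled (blue) and antibody-labelled (orange) libraries, filled where camera at the preset correlation passed. Cholesterol synthesis has the highest median in antibody-labelled libraries, 0.78, against 0.17 in knockout-labelled libraries, and the urea cycle the lowest, -0.41 against -0.08.

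The 268 genes became 119 and 113 without wild-type libraries 1 and 2, 169, 111 and 159 without antibody-labelled libraries 1 to 3, 71 without the trend and robust estimation (1907 at an unadjusted p under 0.05), and 666 with library weights. Of 17 list calls, 0 held with an estimated correlation (4 at an unadjusted p under 0.05). Quantile normalization ended gluconeogenesis (adjusted p = 0.110), acute phase (adjusted p = 0.110) and periportal genes (adjusted p = 0.20). The lack of trend and robust estimation ended the Kupffer (adjusted p = 0.0536) and endothelial (adjusted p = 0.0502) calls.

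The direct contrast, antibody-labelled against knockout-labelled, asks where the labelled groups differ from each other, which passing in one group alone does not show. Cav1 was 2.72 higher on the log2 scale in antibody-labelled libraries (3094 ± 698 against 470 ± 129 normalized counts, SD, n = 3 each, adjusted p = 0.0265). Gcgr was lower at -3.37, and Aass of lysine breakdown was lower at -0.88 (adjusted p = 0.0267). Of 20029 genes, 56 passed, 38 higher and 18 lower, and 2666 had an unadjusted p under 0.05. The groups did not overlap in all 56, as in 17.2% of tested genes, where chance gives 10%. Among the 56, 36 were further from wild type in antibody-labelled libraries and 20 in knockout-labelled libraries. Of the 56, 38 lay on opposite sides of wild type, and 22 passed in neither contrast with wild type. Selecting genes by the difference between the groups favours opposite sides, so the 38 do not show opposed effects. Over all 20029 genes, 65.0% had the same sign in both groups.

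Under the naming rule the other highest were Dsg1c, a desmosomal cadherin with 28 listed paralogs, at 2.24 (adjusted p = 0.0459), the receptor Gpr64 at 2.00 (adjusted p = 0.0158), the channel Hcn3 at 1.78 (adjusted p = 0.0492) and 4930485B16Rik at 1.61 (adjusted p = 0.0356). Its other lowest were 1300015D01Rik at -2.12 (adjusted p = 0.0267), Tfrc at -2.09 (adjusted p = 0.0435), Ugt1a9, a glucuronosyltransferase with 20 listed paralogs, at -1.35 (adjusted p = 0.0119), and the protease Tmprss2 at -1.23 (adjusted p = 0.0470). Elovl5 was lower at -1.01 (adjusted p = 0.0470) and Slc40a1 higher at 0.94 (adjusted p = 0.0267). Sult3a1, a sulfotransferase, was at the floor of 1 in the 3 antibody-labelled libraries against 10.4 ± 0.859 normalized counts in knockout-labelled libraries (SD, n = 3, adjusted p = 0.0356). Over 19 alternatives the call of Gcgr held in all, Ugt1a9 in 17, Cav1 and Gpr64 in 15, 1300015D01Rik in 13, Slc40a1 in 11 and 4930485B16Rik in 10. Those of Tfrc held in 8, Dsg1c in 6, and Elovl5, Hcn3 and Tmprss2 in 4, and that of Sult3a1 held in 8 of 18. Hcn3 (chromosome 3, 88949996 to 88964118, minus strand) overlaps Pklr (88940064 to 88950706, plus strand). In antibody-labelled libraries the means were 785 normalized counts for Hcn3 and 12551 for Pklr. Whether reads of Pklr were counted for Hcn3 was not tested.

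Amino acid catabolism was lower in antibody-labelled than in knockout-labelled libraries, with 3 of 50 genes lower (adjusted p = 4.13e-12, and adjusted p = 0.540 with an estimated correlation) and 15 lower adjusted over the list alone. The 3 were Aass, Mat1a, which makes S-adenosylmethionine, at -0.77 (adjusted p = 0.0469), and Bhmt at -0.80 (adjusted p = 0.0470), while Gls2 was at -0.60 (adjusted p = 0.423). The calls of Aass, Mat1a and Bhmt held in 9, 5 and 4 of 19 alternatives (highest adjusted p = 0.136, 0.182 and 0.190). Against the wild-type mean, the median of the catabolism list was -0.01, -0.35 and 0.03 in knockout-labelled libraries 1 to 3. It was -0.26, -0.30 and -0.35 in antibody-labelled libraries 1 to 3, so knockout-labelled library 2 lay as low as these. The urea cycle list was lower with 0 of 8 past limma's test over all genes (adjusted p = 4.85e-04, and adjusted p = 0.540 with an estimated correlation) and 2 lower adjusted over the list alone, Asl at -1.01 and Ass1 at -0.65, chosen after their values were seen. Cps1 was at -0.52 (adjusted p = 0.282). Fatty acid oxidation and ketogenesis was lower with 0 of 30 past over all genes (adjusted p = 1.05e-11, and adjusted p = 0.540 with an estimated correlation) and 17 lower adjusted over the list alone. They included Ehhadh of peroxisomal oxidation at -0.81 and Cpt1a at -0.37, chosen after their values were seen. Gluconeogenesis was lower with 0 of 15 past over all genes (adjusted p = 2.35e-05, and adjusted p = 0.540 with an estimated correlation). Mdh2 at -0.43, Mdh1 at -0.42 and Ldha at -0.39 were among those lower adjusted over the list alone, enzymes that also act in the citric acid cycle, the malate shuttle or glycolysis, chosen after their values were seen. Pck1 was at -0.70 (adjusted p = 0.338) and G6pc at -0.19 (adjusted p = 0.854).

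Cholesterol synthesis was higher with 0 of 24 past over all genes (adjusted p = 1.01e-05, and adjusted p = 0.753 with an estimated correlation) and 1 higher adjusted over the list alone, Lss at 0.70, chosen after its value was seen. The interferon response was lower with 0 of 21 past, over all genes or adjusted over the list alone (adjusted p = 2.85e-04, and adjusted p = 0.753 with an estimated correlation), and it did not pass without knockout-labelled library 3 (adjusted p = 0.336). The other lists had adjusted p from 0.109 to 0.962, and none of the cell type lists passed. Slc7a2 was at -0.16 (adjusted p = 0.733) and Slc38a5 at -0.88 (adjusted p = 0.497). Fgf21 was at -0.93 (adjusted p = 0.595) and Glul at 0.07 (adjusted p = 0.837). The median, mean and test differed in sign for fatty acid synthesis (0.13, 0.04, down), bile acids (0.04, 0.07, down), the integrated stress response (-0.02, 0.08, down), acute phase (-0.01, 0.04, down) and pancreatic acinar cells (0.23, 0.23, down). The 56 genes became 91 without knockout-labelled library 2, 8 without knockout-labelled library 1, 14 and 16 without wild-type libraries 1 and 2, and 5, 1 and 13 without antibody-labelled libraries 1 to 3. The count was 1 without the trend and robust estimation, 3 with no filter, 19 with library weights, 16 in a fit of only the 6 libraries compared, and 14 with median centring, where 7 were higher and 7 lower.

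The effects of both labelled groups against wild type were compared gene by gene. Of the genes past the threshold in both contrasts with wild type, 8 were higher in both, Aqp8, Ly6d, Eif4e3.1, Rogdi and Slc17a4 among them, and 9 were lower in both, Got1, Slc7a2 and Gm4963 among them. No gene was called in opposite directions. Independent calls would give 0.0857 and 0.119 shared genes, figures that leave the shared controls out of account. Of the 268 genes called in antibody-labelled libraries, 250 (93.3%) had the same sign in knockout-labelled libraries. Of the same genes, 252 had the larger change in antibody-labelled libraries, the group in which they were called. All 31 genes called in knockout-labelled libraries had the same sign in antibody-labelled libraries. Both sets were selected by their change against the same controls, and no simulated share was computed for such a selection. Over all 20029 genes 65.0% had the same sign, against 66.6% in 100 simulations of unchanged groups with the same controls. Across genes, which are not independent replicates, Pearson's r was 0.494 against a simulated mean of 0.499, and Spearman's rho was 0.44. The covariance of the fold changes was 0.0966, above the simulated mean of 0.0681 and the simulated highest of 0.0731, a difference of 0.0285 from the mean. This difference was 0.0136 without wild-type library 1, where the covariance was 0.118 and the simulated highest 0.114, and 0.0526 with library weights. The 3 controls cannot be divided into separate sets of 3, so the shared part was simulated and not removed. Each gene was drawn independently in the simulations, so their range leaves out correlation between genes. A covariance above the simulated highest is therefore no test of a shared effect.

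**Figure D4:**
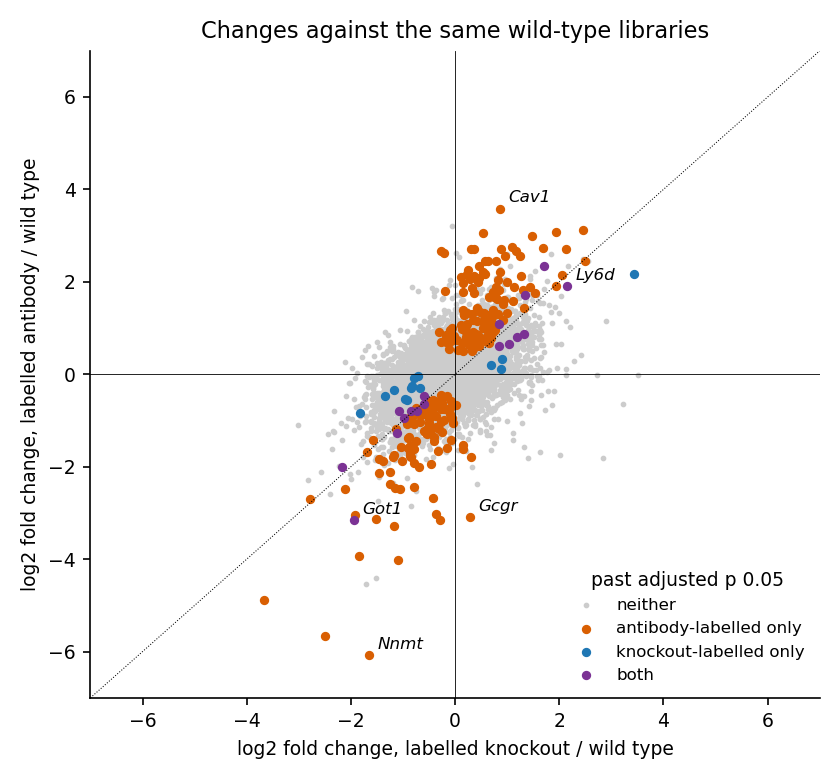
Log2 fold change of 20029 genes in knockout-labelled (x axis) and antibody-labelled (y axis) libraries against the same wild-type libraries, coloured by the contrasts in which a gene passed, with a dotted line of equal change. The 8 genes higher in both and the 9 lower in both lie in the quadrants of equal sign, and Gcgr lies at 0.28 and -3.09.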

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

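The tests in this part were written before their results were seen, apart from the fits that also left out an antibody-labelled library, which were chosen after. In the direct contrast of antibody-labelled with knockout-labelled libraries, limma's test found 56 genes whose change against wild type differed between the groups. Those that the naming rule took, or that are members of a list, had differences in log2 fold change, antibody-labelled minus knockout-labelled, of -3.37 for Gcgr, -2.51 for Sult3a1, -2.12 for 1300015D01Rik, -2.09 for Tfrc, -1.35 for Ugt1a9, -1.23 for Tmprss2, -1.01 for Elovl5, -0.88 for Aass, -0.80 for Bhmt and -0.77 for Mat1a. The positive differences were 0.94 for Slc40a1, 1.61 for 4930485B16Rik, 1.78 for Hcn3, 2.00 for Gpr64, 2.24 for Dsg1c and 2.72 for Cav1. Sult3a1 was at the floor of 1 in every antibody-labelled library, so its difference depends on the pseudocount and is no bound. Groups of 3 libraries were not tested for a library far from the others.

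Gcgr was at 11.8% of wild type in the libraries labelled as antibody-treated and at 123% in those labelled as knockout. The labels of these groups may have been exchanged, or treatment with the antibody may have lowered Gcgr mRNA in correctly labelled libraries while the knockout allele still gave RNA counted for the gene. A knockout allele brought from another strain would leave more called genes near it, and within 10 Mb of Gcgr 3 of 238 genes were called in antibody-labelled against wild type, with 264 of 19790 elsewhere and Gcgr itself left out, an odds ratio of 0.944 (Fisher's exact test, 95% interval 0.192 to 2.82). Among them were Galk1 at 0.70 and Arhgdia at 0.66, chosen after their values were seen, and 0 of the 238 were called by limma in knockout-labelled against wild type. The interval covers both an excess and none, so the explanations cannot be told apart, and every comparison by label carries this doubt.

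Fewer genes were called in knockout-labelled than in antibody-labelled libraries, 31 against 268. The low depth of knockout-labelled library 1 as the cause is argued against by the counts without it, 8 against 288, and by those that also left out antibody-labelled library 1, 2 or 3, which were 7, 2 and 3 against 182, 112 and 171. Effects were smaller in knockout-labelled libraries over 87 amino acid genes, which may account for part of it. Their difference in fold change, signed by direction, had a median of 0.168 (95% bootstrap interval over genes 0.0896 to 0.242, 10000 draws), and 63 genes lay above 0. These genes do not stand for all genes. At an unadjusted p under 0.05 in limma's test the order was reversed, with 2758 genes in knockout-labelled and 2057 in antibody-labelled libraries. Smaller effects over all genes are therefore not shown. Without knockout-labelled library 2 the counts were 154 against 295. The fit shares one spread per gene, so spread from that library raises the SE of both contrasts alike. Got1, for example, had an SE of 0.26 in each. Leaving the library out also moves the knockout-labelled mean, so these counts do not show what its spread contributes. Genes of a list are not independent, and exchanged labels would exchange the groups in this pattern as well.

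The 6 libraries of each contrast can be divided into 2 groups of 3 in 10 ways, too few for a share under 0.1, and 1 of 10 divisions, the real one, gave as many genes in each contrast. In fits of 6 libraries, knockout-labelled against wild type gave 15 genes, with 3 as the highest of the other divisions. Antibody-labelled against wild type gave 363, with 2 as the highest other. Antibody-labelled against knockout-labelled gave 16, with 1 as the highest other.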

How the results depend on the processing

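The weights per library and the voom precision weights were chosen after seeing the data, and the other alternatives before. Of the knockout-labelled genes called against wild type, 31 became 3 with no filter, 0 without the trend and robust estimation (2402 at an unadjusted p under 0.05), 54 with voom precision weights, 15 with only the 6 libraries compared, 14 with an added minimum log2 fold change of 1, and 4 to 154 when a library was left out, the lowest without wild-type library 1 and the highest without knockout-labelled library 2. The 268 antibody-labelled genes became 71 without trend and robust estimation, 666 with library weights, 159 with the minimum fold change and 111 to 295 when a library was left out (lowest without antibody-labelled library 2, highest without knockout-labelled library 2 or 3). The 56 genes of the direct contrast became 3 with no filter, 14 with median centring, 1 without trend and robust estimation, 19 with library weights, 16 with only the 6 libraries, 33 with the minimum fold change and 1 to 91 when a library was left out (lowest without antibody-labelled library 2, highest without knockout-labelled library 2). The minimum fold change lowers counts by its construction, and no filter tests 22423 genes in place of 20029. For the other changes the cause was not tested. A pseudocount of 0.1, a floor of 10, quantile normalization, the replicate block and sums by symbol left all 3 counts within 1.5 times. With median centring, the 12 higher and 19 lower knockout-labelled genes became 12 and 11, the 143 and 125 antibody-labelled genes 114 and 149, and the 38 and 18 of the direct contrast 7 and 7. Median centring and quantile normalization moved the median of all genes by less than 0.1 in each contrast.

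The 6 lists called in knockout-labelled libraries became 1 without trend and robust estimation, 11 with the replicate block, 0 with an estimated correlation, and 4 to 11 when a library was left out (11 without wild-type library 1, 4 without knockout-labelled library 2). With an estimated correlation the 17 and 6 lists of the other contrasts became 0 and 0 as well. Camera then allows for the correlation measured between a list's genes, but this does not account for every loss. In antibody-labelled against wild type, the integrated stress response and the cAMP and CREB responsive genes lost their calls too. Their estimated correlations, 0.00243 and 0.00405, were below the preset 0.01. The skeletal muscle list had 1 tested gene and so no correlation between genes. Its unadjusted camera p in knockout-labelled against wild type still moved from 0.659 to 0.674. The setting therefore changes p apart from the correlation it estimates, so the lost list calls cannot be put down to correlation alone. How much of each loss comes from this was not tested. The median of periportal hepatocyte genes in antibody-labelled libraries turned to 0.0250 without shared genes, and the cause was not tested. The difference between observed and simulated covariance lay between 0.0136, without wild-type library 1, and 0.0526, with library weights, over 19 alternatives, against 0.0285.

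Gcgr kept its direction and call in antibody-labelled against wild type in all 19 alternatives (adjusted p 1.56e-07 to 0.00193), and so did Got1, while in knockout-labelled libraries Got1 kept its call in 12 of 19 (adjusted p 0.0106 to 0.165), Slc7a2 in 10 and Aqp8 in 18. In the counts for named genes that follow, a gene called in neither fit also counts as having kept its call. These counts are therefore not the share of calls that held. Among named genes in all settings but left-out libraries, 151, 387 and 171 values for the 3 contrasts kept direction and call, and 27, 38 and 66 kept the direction alone. When a library was left out, 122, 316 and 130 kept both, and 35, 68 and 85 the direction alone. Among list calls, 57, 179 and 66 values kept both in the settings with all libraries, and 42, 142 and 53 when a library was left out; 15, 24 and 6, and 12, 11 and 1, kept the direction of the test alone. Among the 12, amino acid catabolism kept a test pointing down without knockout-labelled library 2 while its median turned from -0.10 to 0.02. The named genes whose values turned did not pass in the fit with all libraries. Cps1 in knockout-labelled libraries was at -0.010 with quantile normalization and from -0.054 to 0.22 when a library was left out. For Pck1 this range was -0.42 to 0.13 and for Fgf21 -0.25 to 1.10. Slc38a5 in antibody-labelled libraries, near the floor, was at -0.065 with median centring, -0.027 with quantile normalization, -0.026 with library weights, -0.090 with voom precision weights and from -0.16 to 0.18 when a library was left out. In the direct contrast, G6pc ranged from -0.41 to 0.23 when a library was left out, and Glul was at -0.011 with median centring. The cause was not tested for these.

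Libraries with the same replicate number share only that number in the labels. Across genes, their deviations from group means had r of 0.0965, 0.0160 and -0.0143 for knockout-labelled and wild-type libraries 1 to 3, 0.341, 0.0696 and 0.179 for antibody-labelled and wild-type, and 0.124, -0.125 and -0.299 for antibody-labelled and knockout-labelled. Every antibody-labelled library correlated best with the wild-type library of its own number, which the other contrasts did not show. Libraries of unlike numbers also correlated, with r of 0.310 for antibody-labelled library 3 and knockout-labelled library 2. How often such a match arises by chance was not computed, so pairing is not shown. With the replicate block the counts were 38, 251 and 45, of which 22, 208 and 31 genes were shared with the fit without it. Tests on whole reads were not run, since whole reads could not be recovered. At this depth and number of mice, 1.5-fold changes above the median level were called in 9 of 32, 9 of 30 and 13 of 31 simulated genes, so a gene not called is not shown to be unchanged.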

Other observations

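The list tests in this part were set before the results were seen, and the genes named here were chosen after their values were seen. Acute phase genes did not pass as a list in knockout-labelled against wild type (camera adjusted p = 0.0735), with 1 higher and 5 lower of 23 adjusted over the list alone. The higher gene was Orm3 at 2.04 on the log2 scale, and the lower were the metallothioneins Mt2 at -2.82 and Mt1 at -1.77, metal-binding proteins, with Orm2 at -0.88, Saa4 at -0.76 and Steap4 at -0.63. Over all genes, Mt1 and Mt2 had an adjusted p of 0.0663 each, and in antibody-labelled against wild type, where they were at -1.45 and -2.29, of 0.0621 and 0.0582. Growth hormone signalling did not pass in knockout-labelled libraries (adjusted p = 0.0735), with 2 of 12 lower adjusted over the list alone, the growth factor Igf1 at -0.90 and the receptor Ghr at -0.52. Fatty acid synthesis did not pass (adjusted p = 0.185), with 3 of 19 higher adjusted over the list alone, Fasn at 0.85, Dak at 0.67 and Acacb at 0.46, and 2 lower, the desaturases Fads2 at -0.59 and Fads1 at -0.55.

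Of the 268 genes called in antibody-labelled against wild type, 247 are annotated as protein-coding, 9 as long intergenic RNA, 8 as pseudogenes and 4 as antisense RNA, among them 1300015D01Rik. All 31 genes called in knockout-labelled against wild type are annotated as protein-coding. Most tested genes are too, 15845 of 20029, with 955 as long intergenic RNA, 1843 as pseudogenes and 644 as antisense RNA.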
